A study of Mus musculus with 4 samples.

How the data were processed

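Gene expression was measured on 4 Affymetrix mouse arrays, 1 per sample of total RNA from dendritic cells (DC) of the spleen. Per the labels, 3 female C57BL/6 mice per group, aged 8 to 12 weeks, were injected intraperitoneally with 10 µg/kg TCDD or with the DMSO solvent control and killed after 24 h. Spleens were pooled, and DC were enriched on a density gradient and sorted with magnetic beads to a purity above 90%. RNA was amplified before labelling. The 2 DMSO arrays and the 2 TCDD arrays are numbered as biological replicates; whether each array had its own 3 mice is not given in the sources used here.

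The deposited values are RMA values on the log2 scale, per the submitters' processing notes; RMA corrects background, quantile-normalizes between arrays and summarizes the probes of each probe set. The software and its version are not given in the sources used here. All values lie on steps of 0.1, so they had been rounded to 1 decimal. The table holds 22690 probe sets. The 64 Affymetrix control probe sets were left out of the tests, which leaves 22626. By the platform's annotation 20380 of the 22626 probe sets tested have 1 gene symbol, 691 have several and 1555 have none. The probe sets with 1 symbol stand for 12393 genes, of which 4956 have more than 1 probe set. Probe positions along the transcripts were not used here. Arrays give no counts, so the number of arrays limits the precision.

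TCDD was compared with DMSO per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, two-sided). P-values were adjusted by Benjamini-Hochberg over the 22626 probe sets, and a call needed an adjusted p under 0.05. Differences are TCDD minus DMSO on the log2 scale, and each standard error (SE) is the moderated one from limma, with n = 2 arrays per group. The prior had 1.03 degrees of freedom and a standard deviation of 0.107; 741 probe sets had no spread within either group. The p-values measure the spread between arrays. With 2 arrays against 2, an exact permutation test cannot go below p = 0.33 for any single probe set, so none was run. As a description that needs no test, probe sets were counted whose mean log2 difference was at least 1 in size and whose TCDD arrays both lay on the same side of both DMSO arrays.

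The comparison, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. In each direction 15 genes were to be named by size of change among called probe sets with 1 symbol, filled, where too few were called, from probe sets with an unadjusted p under 0.05, no overlap of the groups and a mean log2 value at or above the 40th percentile of all probe sets. That percentile was 5.525. Each gene was named by its probe set of largest change among those that qualified. Every measured AhR target gene was to be named too, with up to 4 members of each other list. In total 29 lists, of pathway genes, of cell type markers and of immediate-early genes as a sign of cell handling, were tested with camera (preset correlation between genes of 0.01) on 1 probe set per gene, the brightest, against all genes with 1 symbol; p-values were adjusted over the 29 lists. The calls were repeated with a correlation estimated from the arrays and with fry, which asks whether a list's genes move one way on balance. A gene on a list can therefore carry another probe set, and another value, than the same gene named by size of change.

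Alternatives were quantile normalization and median centring on top of the deposited values, removal of dim probe sets, a block for the replicate number, a trended robust prior, 1 probe set per gene, the median of a gene's probe sets, other thresholds, the test without moderation and leaving out each array in turn. A crossed replicate block, cyclic loess normalization and a floor on the variance for the rounding were added after the data were seen. An array left alone in its group is assumed to vary like the arrays of the other group. Each list's median was also set against 10000 random lists of genes matched on mean level. Bootstrap intervals of a median drew the genes again 2000 times within the same arrays, so they carry no spread between arrays.

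The fit was tested on simulated data. With a spread of 0.1 in every probe set and unrounded values, limma recovered 100% of probe sets changed by 1, 2 or 3 on the log2 scale. After rounding to 1 decimal it recovered 7.5%, 53.7% and 74.2%. A further run, again rounded, used the moderated spread that limma estimated for each probe set in the real arrays. Moderation pulls large spreads down and small ones up. This run recovered 1.5%, 26.9% and 56.1%. Each run changed 200 probe sets. No unrounded run used the spread of the real arrays. With a shift of 1 on the log2 scale camera called 29 of 29 lists, and with no shift 0. The simulated genes were drawn independently of each other. This run therefore does not test the preset correlation where list members move together: the correlation estimated for MHC class II presentation was 0.694.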

Results

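The comparison asks which transcripts of splenic dendritic cells (DC) differ 24 h after mice received TCDD, a dioxin that binds and activates the aryl hydrocarbon receptor (AhR). Cells from mice given the DMSO solvent were the control, and 2 arrays were run per group. The median log2 value was 5.9 in both DMSO arrays, 6.0 in TCDD replicate 1 and 5.9 in TCDD replicate 2. Across probe sets the DMSO arrays correlated at Pearson's r = 0.982 with each other and the TCDD arrays at 0.953; pairs of a DMSO and a TCDD array gave 0.954 to 0.965. Probe sets are not independent replicates, so these correlations describe likeness of arrays only.

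The largest difference among the named genes was in Ctla2b, which encodes a cysteine protease inhibitor. Its probe set lay at log2 5.4 and 6.7 in DMSO and at 11 and 10 in TCDD, a difference of 4.45 (SE 0.669, n = 2 per group) or 21.9-fold. Ahrr, the AhR repressor and a classical AhR target, lay at 5.5 and 5.2 in DMSO and 7.2 and 7.8 in TCDD, a difference of 2.15 (SE 0.28) or 4.44-fold. Il1r2, the decoy receptor for interleukin-1, was higher by 1.55 (SE 0.212) and Spint1, a serine protease inhibitor, by 1.30 (SE 0.192). On the lower side stood Cd36, a scavenger receptor, with a difference of -1.80 (SE 0.369), Tgfbi, an extracellular matrix protein, with -2.0 (SE 0.369), and the MAP kinase phosphatase Dusp6 with -1.75 (SE 0.323).

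None of these differences passed the test: limma called 0 of 22626 probe sets, with a smallest adjusted p of 0.349. At an unadjusted p under 0.05 there were 2958 probe sets, 1442 higher and 1516 lower in TCDD, or 13.1% of those tested. The test without moderation called 0 as well. With simulated changes of 2 on the log2 scale and the moderated spread of the real arrays the same fit found 26.9%. The count of 0 therefore leaves room for changes of this size.

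In 8462 probe sets both TCDD arrays lay on the same side of both DMSO arrays, 4306 above and 4156 below; that is 37.4%. Chance gives 33.3% for 2 arrays against 2 without ties, and 24.4% with the ties of these rounded values counted. A difference of at least 2-fold without overlap was held by 621 probe sets, 90 higher and 531 lower in TCDD. This split moved with the scaling: quantile normalization gave 133 higher and 246 lower, and cyclic loess, added after the data were seen, gave 100 and 291. Bright probe sets were lower in TCDD in general, with a median difference of -0.35 at DMSO levels from 8 to 10 and of 0.05 below a level of 6. The shift was larger in TCDD replicate 2, at -0.5 for levels 8 to 9 and -0.55 for 9 to 10. In TCDD replicate 1 it was -0.2 at both. Leaving out an array leaves 1 array in its group, where a lack of overlap is easier to meet. Counts with an array left out therefore cannot be set against these.

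The other genes named as higher, none past the threshold, were Vat1 at 2.55, Coro1c at 1.95, the mitochondrial aldehyde dehydrogenase Aldh2 at 1.60, the fatty acid transporter Slc27a2 at 1.5, the antimicrobial peptide gene Camp at 1.35, Serpina1c at 1.30, and Serpina1b and C86187 at 1.15 each. Zfp385a, Tmem214 and Etv3 stood at 1.10 each. In several of them another probe set of the same gene did not share the difference: the brightest other probe set stood at -0.15 for Coro1c, -0.35 for Aldh2, -0.20 for Etv3 and 0.25 for Tmem214. A further probe set of Aldh2 differed by 1.20, and the other one of Serpina1b by 1.25. The other probe sets of Vat1 and C86187 lay below the dim threshold, where a change of the gene need not show. The Ctla2b, Ahrr, Il1r2, Slc27a2, Camp, Spint1, Serpina1c and Zfp385a probe sets had no other of the same single gene. Ctla2a, the close relative of Ctla2b, differed by -0.10 on its own probe set, and a probe set assigned to both genes differed by 1.40; these were looked up after the values were seen.

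The other genes named as lower, again with none past the threshold, began with catalase (Cat) at -2.25, the integrin chain Itgb1 at -2.10, the transcription factor Atf2 at -2.10 and the ETS factor Elf1 at -1.90. Fam107b stood at -1.85, Sypl at -1.80, Stt3a, Klf6 and Rbm39 at -1.75 each, and Acss1, Ube2e2 and Idh1 at -1.70 each. The brightest other probe set shared the direction for Cd36 at -1.55, Sypl at -1.20, Fam107b at -1.0, Atf2 at -0.90, Tgfbi at -0.60, Idh1 at -0.55 and Stt3a at -0.50. It stood closer to 0 for Cat at -0.35, Itgb1 at -0.30, and Klf6 and Rbm39 at 0.05 each, although 2 further probe sets of Rbm39 differed by -1.30. The other probe sets of Acss1 lay below the dim threshold.

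**Figure D1:**
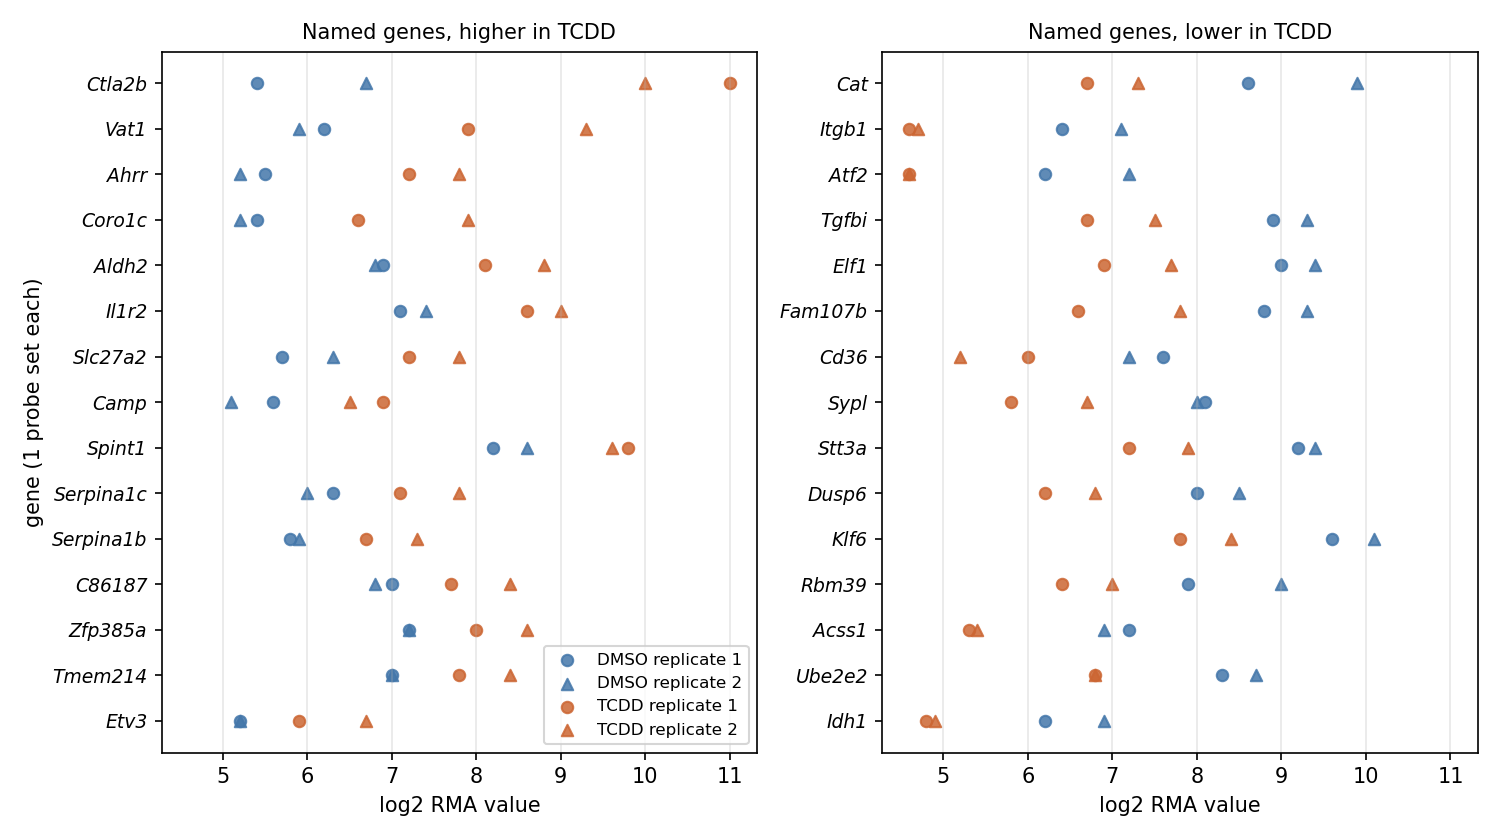
Log2 RMA values (x axis) of the 30 named genes (y axis), 1 probe set each, with 1 point per array; blue marks DMSO, orange TCDD, circles replicate 1 and triangles replicate 2. The groups do not overlap in any of them by the rule that chose them, and the widest gap is that of Ctla2b, at 5.4 and 6.7 against 11 and 10.

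Of 16 AhR target genes fixed for the comparison 12 were measured, and 10 had a difference above 0, but apart from Ahrr the differences were small. Cyp1a1, the cytochrome P450 gene most used as a marker of AhR activity, stayed near the low end of the scale, at 5.3 and 5.3 in DMSO and 5.4 and 5.3 in TCDD. Cyp1a2 differed by 0.10, Cyp1b1 by 0.25 and Nqo1 by 0.15. Cyp1a1, Cyp1a2, Nqo1, Aldh3a1 and Gsta2 lay below the dim threshold, where a change need not show. Tiparp, a further direct target, differed by 0.50, with TCDD replicate 1 at 9.3 and the other 3 arrays at 8.3. Selenbp1 differed by 0.35, Xdh and Aldh3a1 by 0.20 each, Gsta2 by 0.05, Scin by -0.05 and Nfe2l2 by -0.30. The list was not called (camera adjusted p = 0.0788, and adjusted p = 0.55 with an estimated correlation). Without TCDD replicate 2 it was called as higher (adjusted p = 0.0399) and without TCDD replicate 1 it was not (adjusted p = 0.458); over all alternatives run the adjusted p ranged from 0.0399 to 0.55. No member passed over all probe sets, and 0 passed adjusted over the list alone.

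The receptor gene Ahr stood at 8.8 and 9.7 in DMSO and 8.6 and 7.7 in TCDD on its brighter probe set, a difference of -1.10 (SE 0.521), and at 0.45 on its other probe set. Of the other members of the AhR complex list, Src differed by 0.30, Arnt2 by 0.25, Hsp90aa1 by -0.10 and Arnt by 0.00. The list of 5 measured genes had an adjusted p of 0.70; its mean difference was -0.13 while its median was 0.00 and camera's direction was up.

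The list of immediate-early genes, transcription factors and regulators switched on fast by stimulation and included as a sign of cell handling, fell by camera (adjusted p = 0.000471), with 10 of 16 measured genes lower without overlap, 0 higher and a mean difference of -0.77. With an estimated correlation the adjusted p = 0.55. Jun differed by -1.35 (SE 0.444), Ier2 by -1.30 (SE 0.39), Egr1 by -1.05 (SE 0.267) and Klf6 by -1.75 (SE 0.323). The median of the list was -0.93 in TCDD replicate 1 and -0.63 in TCDD replicate 2 against the DMSO mean.

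The cell cycle list fell as well (adjusted p = 0.00143, and adjusted p = 0.55 with an estimated correlation), with 12 of 21 genes lower without overlap, 1 higher and a mean difference of -0.56. The replication helicase gene Mcm6 differed by -1.30 (SE 0.407), the replication clamp gene Pcna by -1.05 (SE 0.607), the topoisomerase gene Top2a by -0.95 (SE 0.48) and Cdc20 by -0.95 (SE 0.684). Cdk1 lay at 7.9 and 7.7 in DMSO and 6.8 and 7.1 in TCDD. The median of the list was -0.35 in TCDD replicate 1 and -0.65 in TCDD replicate 2.

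Both antigen presentation lists fell by camera, and in both the lower values lay mostly in TCDD replicate 1. In that array the neutrophil markers had a median of 0.55 above the DMSO mean, against 0.00 in TCDD replicate 2, with S100a8 at 10.3 against 6.4 and 5.9 in DMSO. For MHC class II presentation (adjusted p = 0.00509, and adjusted p = 0.625 with an estimated correlation) 7 of 12 genes were lower without overlap, and the median was -1.13 in TCDD replicate 1 and -0.25 in TCDD replicate 2. The invariant chain gene Cd74 lay at 13.2 and 12.5 in DMSO and at 10.9 and 12.6 in TCDD; the lysosomal protease gene Ctsl differed by -1.45 (SE 0.458), H2-Oa by -1.0 (SE 0.355) and Lgmn by -0.90 (SE 0.572). For MHC class I presentation (adjusted p = 0.0234, and adjusted p = 0.625 with an estimated correlation) 5 of 14 genes were lower without overlap, and the medians were -0.80 and -0.23. Pdia3 lay at 9.8 and 9.7 in DMSO and at 6.0 and 8.9 in TCDD, H2-D1 differed by -1.40 (SE 0.953), Psmb8 by -1.0 (SE 0.645) and Erap1 by -0.90 (SE 0.35).

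Markers of type 1 conventional DC (cDC1), the subset that cross-presents antigen, fell by camera (adjusted p = 0.00202, and adjusted p = 0.55 with an estimated correlation), with 5 of 10 genes lower without overlap and a mean difference of -0.56. Naaa differed by -1.45 (SE 0.255), Cd24a by -0.90 (SE 0.143), Batf3 by -0.60 (SE 0.35) and Tlr3 by -0.60 (SE 0.442). Markers of macrophages and monocytes fell too (adjusted p = 0.0208, and adjusted p = 0.55 with an estimated correlation), with 6 of 16 genes lower without overlap and a mean of -0.53. The iron exporter gene Slc40a1 differed by -1.15 (SE 0.513), the heme oxygenase gene Hmox1 by -1.10 (SE 0.131), Lyz2 by -1.05 (SE 0.659) and C1qa by -0.90 (SE 0.467). The markers of type 2 conventional DC (cDC2) were not called as a list (adjusted p = 0.0932), except without TCDD replicate 2 (adjusted p = 0.0466; range over the alternatives 0.0466 to 0.564). Among them Dtx1 at -1.15 (SE 0.179) and Sirpa at -1.05 (SE 0.159) gave 2 genes that passed adjusted over the list alone and 0 over all probe sets; Klf4 differed by -1.05 and Irf4 by -0.50. In the other 28 lists 0 genes passed adjusted over the list alone.

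With an estimated correlation 0 of the 29 lists were called, and fry called 0. Without TCDD replicate 1 camera called 0 lists, and without DMSO replicate 1 it called 2. Without TCDD replicate 1 the mean difference of the immediate-early list was -0.63, of cell cycle -0.65, of cDC1 -0.57 and of macrophage and monocyte markers -0.52, against -0.77, -0.56, -0.56 and -0.53 with all arrays, while MHC class II went from -0.70 to -0.40 and MHC class I from -0.68 to -0.28. The MHC class I call was also lost under quantile normalization at a mean of -0.39, cyclic loess at -0.41 and the median of each gene's probe sets at -0.52. It was lost at an undiminished mean under median centring (-0.73), removal of dim probe sets and the replicate block (-0.68 each). The MHC class II call was lost under cyclic loess at -0.46. The macrophage and monocyte call was lost at an undiminished mean under median centring (-0.58), removal of dim probe sets (-0.53) and without TCDD replicate 2 (-0.54). Without DMSO replicate 1 the calls of both MHC lists and of macrophage and monocyte markers were lost at smaller means. These were -0.45 for MHC class II, -0.51 for MHC class I and -0.45 for macrophage and monocyte markers. TCDD replicate 1 also stood apart in its control probe sets for Gapdh and beta-actin. The 3′ end exceeded the middle of Gapdh by 3.6 on the log2 scale, against 1.5 and 2.1 in DMSO and 2.0 in TCDD replicate 2. For beta-actin the gap was 4.0, against 1.9 and 2.1 in DMSO and 2.0 in TCDD replicate 2. The mean level of the 6 dap control probe sets was 6.2 in TCDD replicate 1 and 5.0 in TCDD replicate 2. It was 5.9 and 7.7 in DMSO replicates 1 and 2. A mean level does not show a gap along a transcript, so it cannot speak for or against such a gap.

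**Figure D2:**
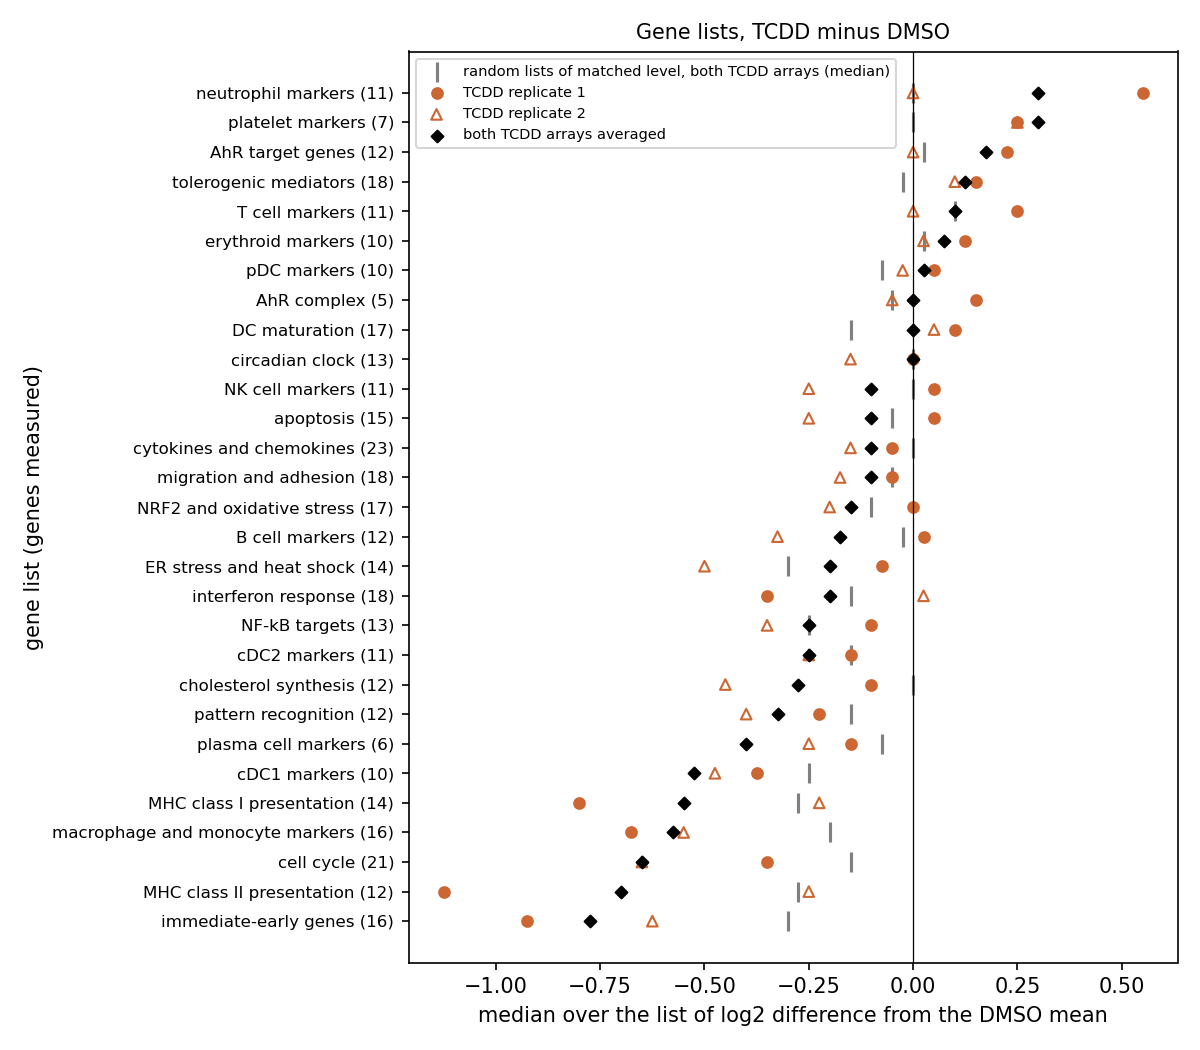
Median over each gene list (y axis, with the number of genes measured) of the log2 difference from the DMSO mean (x axis); filled circles are TCDD replicate 1, open triangles TCDD replicate 2, diamonds both averaged and grey ticks the median of random lists matched on mean level. The MHC class II list lies at -1.13 in TCDD replicate 1 and at -0.25 in TCDD replicate 2, while the cell cycle list lies at -0.35 and -0.65.

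**Figure D3:**
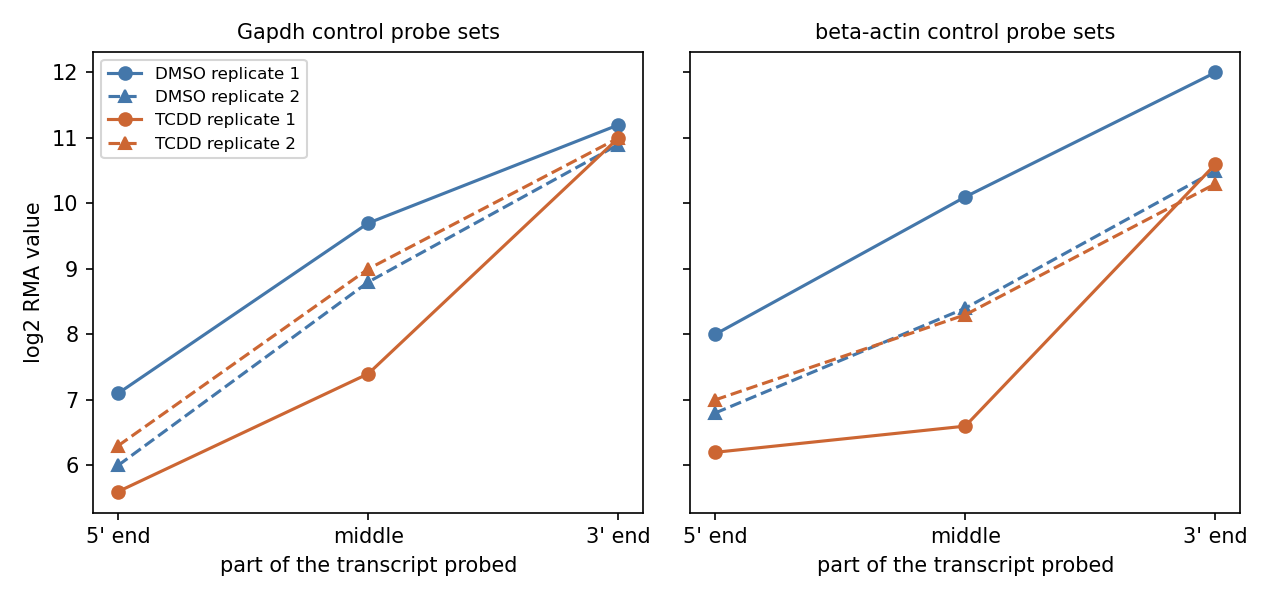
Log2 RMA values (y axis) of the control probe sets for the 5′ end, the middle and the 3′ end (x axis) of the Gapdh and beta-actin transcripts, with 1 line per array. In TCDD replicate 1 the middle of beta-actin lies at 6.6, against 10.1, 8.4 and 8.3 in DMSO replicate 1, DMSO replicate 2 and TCDD replicate 2, while its 3′ end at 10.6 lies within the range of the others.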

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

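The test of sibling probe sets was planned before its result was seen; the count of splits at the end was chosen after it. Control probe sets of TCDD replicate 1 showed a larger loss of signal from the 3′ end to the middle and the 5′ end than both DMSO arrays. For Gapdh the 3′ end exceeded the middle by 3.6 on the log2 scale (highest DMSO value 2.1) and the 5′ end by 5.4 (highest DMSO value 4.9). For beta-actin these gaps were 4.0 (highest DMSO value 2.1) and 4.4 (highest DMSO value 4.0).

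The same array held 105 probe sets at least 1.5 lower on the log2 scale than in each of the other 3 arrays, against 0, 1 and 17 in DMSO replicate 1, DMSO replicate 2 and TCDD replicate 2. In 48 genes with a bright second probe set, the probe sets that defined the pattern had a median of -2.43 in TCDD replicate 1, and the brightest other probe set of the same gene had a median of -0.18 (95% bootstrap interval -0.45 to 0). A labelled product shortened at the 5′ side in that array would give this. Choosing probe sets for low values in that array would also give it, because noise in the chosen ones is not shared by their siblings. The test cannot separate the 2. These siblings had a median of -0.475 in TCDD replicate 2. In 39 of the 48 genes the probe set that defined the pattern was the dimmer one. The sibling was chosen as the brightest other probe set, at a DMSO mean of at least 8, which favours this. The positions of the probe sets were not used here, so other differences between probe sets of a gene stay open. An effect of TCDD itself on these probe sets stays open too, as untested. An example chosen after its values were seen is the class II beta chain gene H2-Ab1, with a probe set at 11.9 and 10.3 in DMSO and 6.5 in TCDD replicate 1, and another at 12.9 and 12.4 in DMSO and 12.1 in TCDD replicate 1.

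At an unadjusted p under 0.01 limma found 542 probe sets between TCDD and DMSO, or 2.4% of those tested. Such a threshold passes a share of about 0.01 where nothing differs. The other splits of the 4 arrays gave at most 75. In those splits a difference between TCDD and DMSO adds to the spread within groups and lowers the count. They therefore do not show what would be found with no difference. Of the 3 splits only 1 gave as many, the real one, and 3 splits are too few for a share under 0.05.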

How the results depend on the processing

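Cyclic loess, the crossed replicate block and the variance floor were chosen after the data were seen. Limma called 0 probe sets under quantile normalization, median centring, removal of dim probe sets, the replicate block, the trended robust prior, 1 probe set per gene, an adjusted p under 0.10, no moderation, each array left out and the 3 added settings. At an unadjusted p under 0.01 there were 542 probe sets, 194 higher and 348 lower. Whether the replicate numbers pair the arrays is not given in the sources used here. Replicate 1 minus 2 correlated at -0.189 between the groups across probe sets, a single value that cannot decide it. The crossed pairing called 0 probe sets. Of the 2-fold differences without overlap, the higher ones went from 90 to 594 at 1.5-fold and ranged from 82 to 326 with 1 array left out. The lower ones went from 531 to 246 under quantile normalization, 291 under cyclic loess and 1894 at 1.5-fold, and ranged from 652 to 942 with 1 array left out. Camera's 6 lists became 0 with an estimated correlation and 0 with fry, 5 with the replicate block (MHC class I lost), and ranged from 0 to 8 with 1 array left out (0 without TCDD replicate 1, 2 without DMSO replicate 1). Without TCDD replicate 1 the calls of cell cycle, cDC1, macrophage and monocyte markers and immediate-early genes ended. Their mean differences were -0.65, -0.57, -0.52 and -0.63, against -0.56, -0.56, -0.53 and -0.77 with all arrays. Without DMSO replicate 1 the call of cDC1 ended at -0.54. The calls of MHC class II, MHC class I and macrophage and monocyte markers ended there too, at -0.45, -0.51 and -0.45. With all arrays these means were -0.70, -0.68 and -0.53. Leaving out an array leaves fewer arrays to test; for the other shifts the cause was not tested. In simulated data with the same spread of 0.1 in every probe set, rounding to 1 decimal lowered the share recovered at a change of 1 from 100% to 7.5%. No unrounded run used the spread of the real arrays, so how far the rounding limits detection here was not tested.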

Other observations

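The tests of this part were planned before their results were seen, with 4 exceptions chosen after: the dim threshold and the level trend for sibling probe sets, the reading of percentiles from 2.5 to 25 as open where the plan had set 2.5 alone, and the use of the percentile in TCDD replicate 1. The lists below were not called with all 4 arrays and the preset correlation, and each is given with some of its members of largest change, none past the threshold. Among cytokines and chemokines (adjusted p = 0.229) Il1b differed by -1.30, Ccl3 by -1.0 and Cxcl9 by -0.80. Among NF-kB targets (adjusted p = 0.0932) the adaptor gene Traf1 differed by -1.05. Among DC maturation genes (adjusted p = 0.897) the costimulatory gene Cd80 differed by -1.0, Cd83 by -0.60 and Socs2 by 0.60, with no common direction, and among pattern recognition genes (adjusted p = 0.285) the beta-glucan receptor gene Clec7a by -1.0. The interferon response (adjusted p = 0.163) held Mx1 at -0.90; the list was called as lower without TCDD replicate 2 (adjusted p = 0.00162; range over the alternatives 0.00162 to 0.746, with either direction). Tolerogenic mediators (adjusted p = 0.126) held Socs1 at 0.65, Socs2 at 0.60, Tnfaip3 at 0.45 and Ido1 at 0.45. Of the NRF2 and oxidative stress genes (adjusted p = 0.107) Hmox1 differed by -1.10, Sod1 by -0.70 and Gclc by -0.50. In the circadian clock list (adjusted p = 0.608) Nr1d2 differed by -1.45 and Per2 by 0.80, and in cholesterol synthesis (adjusted p = 0.32) Msmo1 differed by -0.70. Migration and adhesion had an adjusted p of 0.414 with Itgb2 at -0.85, apoptosis 0.621 with Casp8 at -1.10, and ER stress and heat shock 0.163 with Hsp90b1 at -0.85. The last was called as lower with the median of each gene's probe sets (adjusted p = 0.0198; range 0.0198 to 0.979, with either direction).

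Markers of other spleen cells were not called as lists. The adjusted p was 0.58 for plasmacytoid DC, 0.621 for B cells, 0.394 for plasma cells, 0.394 for T cells, 0.553 for NK cells and 0.163 for erythroid cells. Platelet markers had an adjusted p of 0.0932, with Pf4 at 0.60 and Gp9 at 0.40. The neutrophil list had an adjusted p of 0.163, with a median at percentile 99.6 of random lists over both TCDD arrays, 100 in TCDD replicate 1 and 77.7 in TCDD replicate 2. Camp was higher in both (5.6 and 5.1 in DMSO, 6.9 and 6.5 in TCDD), while S100a8 lay at 6.4 and 5.9 in DMSO and at 10.3 and 5.6 in TCDD, and S100a9 at 6.4 and 5.6 in DMSO and at 9.6 and 5.3 in TCDD. The other 9 neutrophil markers had a median of 0.30 in TCDD replicate 1 (95% bootstrap interval -0.1 to 1.55), which leaves open whether neutrophils that passed the sort were the source.

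Probe sets at least 2-fold higher in TCDD without overlap were seldom followed to that size by their siblings. In 51 genes with another probe set the higher one had a median difference of 1.20 and the brightest other one a median of 0.05 (95% bootstrap interval -0.1 to 0.1); with 14 siblings below the dim threshold left out, the median over 37 was 0.05 again (-0.1 to 0.1), and 1 of the 37 was 2-fold higher too. Set against probe sets of like level, which were lower in TCDD, those 37 siblings stood at 0.15 (0.05 to 0.25) and the higher probe sets at 1.30; on the 2-fold lower side the siblings in 277 genes had a median of -0.40 (-0.45 to -0.35), 27 of them 2-fold lower too, and stood at -0.20 (-0.25 to -0.1) against the trend, where the lower probe sets stood at -1.05. Signal of single probe sets, such as a transcript variant or cross-hybridization, and a smaller change of the gene cannot be told apart on the higher side. The siblings lay slightly above the trend there, with an interval that resamples genes and carries no spread between arrays. Choosing probe sets for a large difference in these same arrays would also leave smaller differences in their siblings, which do not share the noise. The test cannot separate this from the other explanations, on the higher or the lower side. Other splits of the arrays gave 107 and 263 probe sets at least 2-fold different without overlap, against 621 between TCDD and DMSO. A probe set without overlap in 1 split overlaps in the others, so a difference between TCDD and DMSO lowers those counts. An effect of TCDD on a variant stays open. Genes with 1 probe set, among them Ctla2b, Ahrr and Il1r2, were outside this test.

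The 6 lists called as lower may partly reflect 2 features of the arrays, the lower values of bright genes in TCDD and the values of TCDD replicate 1. Against random lists of equal mean level, the median over both TCDD arrays lay at percentile 0.11 for MHC class II. The percentile was 0 for cell cycle, 0.01 for immediate-early genes and 0.21 for macrophage and monocyte markers. For MHC class I it was 3.55 and for cDC1 4.57. Among the lists not called the lowest was 1.52, for cholesterol synthesis. The 6 lists were picked as lower in these same arrays, which favours low percentiles. Random lists also leave out any correlation between list members. Whether brightness alone accounts for the 6 lists therefore stays open. In TCDD replicate 2 alone the percentile was 91.5 for MHC class II and 97.1 for MHC class I, against 0 and 0.17 in TCDD replicate 1 alone, as a change carried by TCDD replicate 1 would give. These lists depended on DMSO replicate 1 too. Without it the mean difference was -0.45 for MHC class II and -0.51 for MHC class I, against -0.70 and -0.68 with all arrays. For cDC1 the percentile in TCDD replicate 2 alone was 34.7 against 8.19 in TCDD replicate 1, with medians of -0.48 and -0.38, which does not single out either array. It was 7.58 for immediate-early genes and 7.04 for macrophage and monocyte markers, which leaves that question open, and 0.23 for cell cycle, which was low in both TCDD arrays. The size of the cell cycle difference depended on the DMSO arrays. Its mean was -0.405 without DMSO replicate 2 and -0.724 without DMSO replicate 1, against -0.564 with all arrays. Random lists ignore that list members move together, so these percentiles describe the 4 arrays only, and lower cell cycle transcripts after TCDD remain a hypothesis.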
